A study of Oryza sativa Japonica Group with 32 samples.

How the data were processed

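The series measured gene expression in leaves of rice (Oryza sativa Japonica, cultivar Nipponbare) on 16 Agilent 2-colour arrays spread over 4 slides. Per the labels, each of the 32 samples was labelled with 1 dye, so that each array carried 2 different samples and no common reference was used. Per the labels' protocols, seedlings were transplanted into a paddy field at Tsukuba, and some were moved into containers there before treatment. Oryzemate granules (24% probenazole) and Routine granules (3% isotianil) were given at 1 kg per are in the field and in containers. V-get granules (6% tiadinil) were given at 3 kg per are, Bion (5% acibenzolar-S-methyl, called BTH in the labels) at 100 ppm, and ethanol at 1%, in containers alone. Field leaves were taken before treatment (day 0) and on days 1, 3, 7, 14 and 30, and container leaves on days 1 and 3. Total RNA was extracted with the RNeasy Mini Kit and labelled with the Quick Amp kit, per the labels' protocols.

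The deposited scanner files hold spot intensity values in both channels, which the authors extracted with Agilent Feature Extraction 10.5.1.1, per the file headers. The mean signal and the median local background of each spot and channel were used here. A value table of the series, also in intensity units as deposited by the authors, holds 1 value per gene and sample. Its columns had medians between 297.46 and 300.04, and on 19497 loci with a single probe their lowest correlation with the scanner's processed signal was 0.994, so the table was taken as linear. The centring behind those medians is not given in the sources used here, and the table served as an alternative only. The array design names rice loci by identifiers of the Rice Annotation Project (RAP), with short descriptions, and these names were kept as the files give them. Symbols came from gene lists written in advance, and no genome was used.

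Each array had 43734 spots apart from controls, for 42477 probes, of which 41908 were tied to 29690 RAP loci. Background was corrected with normexp (offset 50), each array was normalized by loess with control spots at weight 0, and arrays were scaled with Aquantile, all in limma 3.58.1 under R 4.3.3 with version 1.17.8 of the data.table package. Spots marked as outliers in their channel (0.194%) were left out, and spots of 1 probe were averaged. The text uses 1 probe for each locus, namely the probe with the highest mean over the 32 samples among those measured in all of them. For 252 loci every probe had a missing value, and these loci were left out. A locus was tested if its probe was well above background in at least 2 of the 32 samples, which 26075 loci were. A probe not well above background in all samples of 1 side gives only a bound, written as "at least N-fold"; it sets the brighter mean against the higher of the dim probe's signal and the lowest signal among probes well above background.

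The samples were compared with limma's linear models and empirical Bayes test on log2 intensities of the separate channels, two-sided, with Benjamini-Hochberg adjustment over the 26075 loci and calls at an adjusted p under 0.05. Dye was a fixed term, and the array was a random block with a consensus correlation of 0.336. An additive model over setting, day and treatment (16 residual and 2.85 prior degrees of freedom) gave the effects over days and in containers. A model with 1 mean for each group of treatment, setting and day (28 groups, 3 residual and 2.73 prior degrees of freedom) gave the effects at field day 3, the differences between late and early days, and those between containers and field. Only untreated day 1 and the 3 treatments at field day 3 had 2 samples each, and every other group had 1. Container days stood in for replicates, and each container treatment lay on 1 array, so the spread of a treatment between arrays could not be measured in containers. Field plots are not described in the labels beyond the word section, so it is not known whether the 2 samples of a group came from different plots. The p-values therefore measure the spread between these samples, which may be technical in part.

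In total 22 comparisons were made, and 22 gene lists were tested in each. The lists were WRKY45 pathway and salicylic acid (SA) signalling, PR (pathogenesis-related) proteins, diterpenoid phytoalexins, phenylpropanoid entry, jasmonate, abscisic acid and water deficit, photosynthesis, nitrogen assimilation, floral induction, leaf senescence, circadian clock, heat shock, alcohol and low-oxygen metabolism, phosphate starvation, iron homeostasis and dividing tissue. A further 6 were families taken from the array's descriptions, namely WRKY factors, glutathione S-transferases, cytochromes P450, UDP-glycosyltransferases, peroxidases and ribosomal proteins. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists, and again with an estimated correlation, and with fry. One list member, Os04g0614600, was left out, because its description on the array did not match the product meant. Genes were named by a rule that took, for each comparison, up to 10 called genes with the largest rise and 10 with the largest fall, leaving out those with neither symbol nor description. With fewer than 3 calls it took the 5 genes of smallest p, as values. It also took up to 4 members of each list with the largest absolute change, and WRKY45, WRKY62, NPR1, PR1a, PR1b and PBZ1/PR10a in every treatment comparison. The lists, the naming rule, the comparisons, the models and most alternatives were chosen before the data were examined. One result for a single gene is not reported here.

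Among the alternatives were no filter and 2 stricter filters on dim probes, 3 other scalings (the processed signal scaled to its 75th percentile, loess followed by that percentile, and the authors' value table), and models without the dye term or without the array block. The slide was also used as a fixed block, slides were fitted alone, and the replicate number was used as a block. Samples and days with more than 1 fit possible were left out in turn. Settings added after the data were seen were the filter on all 32 samples, the omission of the Routine sample of field day 7, and a crossed replicate block. Calls on loci with several probes were set against the other probes of the same locus. Container samples were also set against untreated field plants of days 1 and 3. Comparisons that share controls were set against 20 simulations without effects. The whole procedure was tested on simulated data, in which 100 of 26075 loci were changed by 1 log2 unit and 100 by 2 units for each comparison tried. For field Oryzemate it recovered 92 and 100 of them, with 13 false calls. For Routine in the field it recovered 91 and 99, with 12 false calls. At field day 3 with Oryzemate it recovered 41 and 80, with 6 false calls. For BTH against untreated containers it recovered 75 and 93, with 9 false calls, and against ethanol 65 and 96, with 11. Depth, in the sense of reads, does not apply to arrays, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.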

Results

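Plant activators were given to rice in a paddy field and in containers, and leaf RNA was compared with that of untreated plants over 30 days in the field and over 3 days in containers. The field part held 6 samples with Oryzemate, 6 with Routine and 7 untreated samples of the same days, with 1 more untreated sample from before treatment. Days 1, 7, 14 and 30 had 1 sample for each treatment, except that untreated day 1 had 2, and day 3 had 2 samples for each treatment. The container part held 2 samples, from days 1 and 3, for each of untreated plants, Oryzemate, Routine, BTH, V-get and ethanol. All values are log2 ratios of intensity between groups, with the standard error (SE) or the adjusted p where given, for 26075 loci. With arrays, the number of arrays limits the precision, and the median SE over all loci was 0.09 for Oryzemate and 0.091 for Routine over the field days, 0.132 and 0.146 at field day 3, and 0.168 in containers. The 32 samples had 72.4 to 86.13% of their probes well above background. Samples of the same group and day correlated at 0.9922 (untreated day 1), 0.9954 (untreated day 3), 0.994 (Oryzemate day 3) and 0.9891 (Routine day 3). In a principal component analysis with 26.1 and 21.2% of the variance on the first components, the Routine sample of field day 7 stood apart, at -70.9 on the second.

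The first question was which genes differed between Oryzemate-treated and untreated field plants over days 1 to 30. The gene Os04g0468600 rose by 2.01 (SE 0.342, adjusted p = 0.042), a kinase gene, Os03g0703200, by 0.50 (SE 0.07, adjusted p = 0.0126), and the copine gene Os06g0608800 by 0.47 (adjusted p = 0.0355), each higher in 6 of 6 treated samples. The cytochrome P450 gene Os01g0227800 fell by 0.62 (SE 0.097, adjusted p = 0.0327), and Os03g0337200 fell by 0.53 (adjusted p = 0.0126), both lower in 6 of 6 samples. Smaller falls were those of the basic helix-loop-helix (bHLH) gene Os05g0103000 (-0.40), an exonuclease gene, Os04g0650600 (-0.38), the DNA repair gene MRE11, Os04g0635900 (-0.28), and Os01g0788900 (-0.27). In total 12 genes passed the test, 5 higher and 7 lower, and 1 of them changed at least 2-fold. WRKY45 (1.02, SE 0.295, adjusted p = 0.0949), WRKY62 (1.66, SE 0.481, adjusted p = 0.0949), NPR1 (0.57, adjusted p = 0.111), PR1a (1.05, SE 0.359, adjusted p = 0.137) and PR1b (1.73, SE 0.487, adjusted p = 0.0928) did not pass, although each was higher in 6 of 6 samples. The mean log2 intensity of WRKY45 was 14.93 ± 0.56 (SD) in treated and 13.87 ± 0.34 in untreated samples, and that of WRKY62 was 10.29 ± 0.85 and 8.57 ± 0.45. PBZ1/PR10a was at 0.40 (SE 0.193, adjusted p = 0.272), higher in 5 of 6 samples.

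As a group, the 12 genes of SA signalling and the WRKY45 pathway lay higher under Oryzemate, with a median of 0.52 and 11 of 12 members above 0, SGT1 at 1.44 among them. The median of the list was higher in each of the 6 samples (0.159 to 0.747). Limma's camera gave the list an adjusted p of 6.04e-07, with adjusted p = 0.037 with an estimated correlation and 0.00583 with fry. No member passed over all loci, and 7 did when adjusted over the list alone. Of the 26 genes for PR proteins 23 were higher, among them the glucanase gene Os01g0940800 (1.40), PR5 (1.24) and PR8 (1.08). Camera gave the PR list 6.67e-10, with adjusted p = 0.113 with an estimated correlation, and 9 members passed over the list alone. The phenylpropanoid entry list had a median of 0.69 with 10 of 11 genes higher, PAL Os02g0627100 at 1.08 among them. Its camera result was 7.12e-05, with adjusted p = 0.196 with an estimated correlation, and 4 members passed over the list alone. Diterpenoid phytoalexin genes had a median of 0.29, with CYP99A2 at 1.40, MAS at 1.24, CPS4 at 1.19 and KSL4 at 1.12 (camera 6.99e-05, with adjusted p = 0.277 with an estimated correlation). The 58 glutathione S-transferases had a median of 0.10 (camera 1.64e-05, with adjusted p = 0.0276 with an estimated correlation), with Os10g0528100 at 1.12 and Os10g0531400 at 1.08, and 8 rose and 2 fell over the list alone.

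The WRKY family under Oryzemate had a positive median in the fit reported here and a negative one (-0.06) under loess with the 75th percentile, where the median of all genes was -0.107, with WRKY76 at 1.92 (adjusted p = 0.0752). Camera gave the family 1.45e-05, with adjusted p = 0.113 with an estimated correlation, and 15 members passed over the list alone. Camera also called the jasmonate list (0.11, 0.0277, with adjusted p = 0.488 with an estimated correlation), LOX Os08g0508800 being at 1.25. The photosynthesis list was called as well (0.04, 0.0419, with adjusted p = 0.733 with an estimated correlation). The 8 genes of the circadian clock were all lower, with a median of -0.14, LHY in 6 of 6 samples (camera 0.0204, with adjusted p = 0.404 with an estimated correlation). Dividing tissue markers had a median of 0.16, which that scaling turned negative, and camera gave 0.021, with adjusted p = 0.277 with an estimated correlation. UDP-glycosyltransferases had a median of 0.01, negative under 2 other scalings (lowest -0.11; camera 0.0277, with adjusted p = 0.113 with an estimated correlation), with Os01g0176000 at 1.22. Peroxidases had a median of 0.07, negative (-0.14) under that scaling (camera 0.0178, with adjusted p = 0.29 with an estimated correlation). The lists that camera did not call were abscisic acid and water deficit (median 0.05, mean -0.04), nitrogen assimilation (NIA1 -0.44, NIA2 -0.36), floral induction (-0.13), leaf senescence (-0.15), heat shock, alcohol and low-oxygen metabolism (mean -0.02, positive median), phosphate starvation (0.02) and iron homeostasis (-0.13). Nor did it call cytochromes P450 (-0.02, with 1 member, Os01g0227800, fallen and Os04g0339000 at 1.82) and ribosomal proteins (0.01).

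The count of 12 for Oryzemate rested on few samples. Without field day 1, 7, 14 or 30 it was 119, 3, 3 and 0. Without 1 sample of field day 3 it was 43 (Oryzemate replicate 2), 1 (Oryzemate replicate 1), 1 (untreated replicate 1), 2 (untreated replicate 2), 2 (Routine replicate 1) and 5 (Routine replicate 2), and it was 83 without untreated day 1 replicate 2 and 130 without Routine day 7. The processed signal gave 71 higher and 38 lower, the values deposited by the authors gave 316 calls, and loess with the 75th percentile gave 0 in limma (4074 loci at an unadjusted p under 0.05). Within slides 1 and 2 alone 0 genes passed in limma, but these fits held few samples, so the count of 0 says little. Slide 3 held only 1 Oryzemate sample. With slide as a block 1792 genes passed, while 4996 loci had an unadjusted p under 0.05 in the fit over all slides. On loci with other probes, these moved by 108% of the called probe's change for 3 rises and by 27.2% for 2 falls (34.6% over the 5 loci).

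Routine was set against the same untreated field samples. In these plants WRKY28 rose by 1.22 (SE 0.222, adjusted p = 0.0455), another WRKY gene, Os03g0335200, by 2.07 (SE 0.40, adjusted p = 0.0456) and WRKY19 (Os05g0571200) by 1.59 (adjusted p = 0.0456). The mean of WRKY28 was 8.48 ± 0.82 in treated and 7.21 ± 0.42 in untreated samples, that of Os03g0335200 was 9.26 ± 1.19 and 7.04 ± 0.30, and all 3 genes were higher in 6 of 6 samples. Large rises were also those of Os02g0718100 (2.65, adjusted p = 0.0456), Os04g0468600 (2.36, SE 0.348, adjusted p = 0.0122), a pepsin-like protease gene, Os07g0532800 (2.02). Others were an AAA ATPase gene, Os12g0431100 (1.69), a dioxygenase gene, Os04g0581000 (1.64), and an acetyltransferase gene, Os03g0664800 (1.48). A phosphoinositide kinase gene, Os04g0691900, fell by 0.78, Os03g0337200 by 0.57 (adjusted p = 0.00391, lower in 6 of 6 samples). Smaller falls were those of an ABI5-like gene, Os09g0456200 (-0.41), a homeodomain leucine zipper gene, Os03g0640800 (-0.41), a transferase gene, Os02g0484600 (-0.36), and a P450 gene, Os06g0267400 (-0.33). With Routine 62 genes passed, 52 higher and 10 lower, and 21 of them changed at least 2-fold. WRKY45 was higher in 5 of 6 samples, by 1.14 (SE 0.299, adjusted p = 0.0741), and did not pass. Nor did WRKY62 (1.65, adjusted p = 0.0979), NPR1 (0.69, adjusted p = 0.0741), PR1a (1.23, adjusted p = 0.0985), PR1b (1.11, SE 0.494, adjusted p = 0.279) and PBZ1/PR10a (0.50, adjusted p = 0.219), each higher in 6 of 6 samples.

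Under Routine the SA signalling and WRKY45 pathway list had a median of 0.61, and 1 member rose over all loci and 10 over the list alone. The list median was higher in 6 of 6 samples (0.228 to 1.073), and camera gave 6.91e-08, with adjusted p = 0.0306 with an estimated correlation. The WRKY family, with medians of 0.012 to 0.181 over the scalings, had 4 members risen and 22 over the list alone, with WRKY76 at 1.83 (camera 2.57e-08, with adjusted p = 0.0306 with an estimated correlation). Among glutathione S-transferases, whose median of 0.06 was negative (-0.03) under loess with the 75th percentile with the median of all genes at -0.112, 2 rose, Os10g0531400 among them, and 11 passed over the list alone (camera 0.00029, with adjusted p = 0.0306 with an estimated correlation). PR proteins had a median of 0.52 (0.137 to 0.868 over the samples). Diterpenoid phytoalexin genes had a positive median, with -0.04 to 1.639 over the samples, the highest on day 7 in the sample that stood apart. Members were RSOsPR10 at 1.33 (adjusted p = 0.0571) in the former list and, in the latter, CYP99A2 at 1.66, MAS at 1.45, CPS4 at 1.43 and KSL4 at 1.16. Camera gave 6.61e-06 and 4.07e-07 for these, with adjusted p = 0.362 and 0.239 with an estimated correlation, and 9 and 8 members passed over the list alone. The jasmonate list (0.20, with LOX Os08g0508800 at 1.62) and the circadian clock, all 8 genes lower, were called with 0.00949 and 0.0353, with adjusted p = 0.562 and 0.568 with an estimated correlation. Camera did not call phenylpropanoid entry (0.22, 0.0513), abscisic acid and water deficit (-0.07), photosynthesis (0.06), nitrogen assimilation (median -0.03, mean 0.02; NIA1 -0.53, NIA2 -0.39), floral induction (0.04), leaf senescence (-0.02), heat shock (-0.04), or alcohol and low-oxygen metabolism (median -0.01, mean 0.05). It did not call phosphate starvation (median -0.04, mean 0.05), iron homeostasis (-0.25), dividing tissue (0.11), cytochromes P450, UDP-glycosyltransferases, peroxidases or ribosomal proteins (0.04).

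The Routine count of 62 became 605, 2, 7 and 7 without field day 1, 7, 14 or 30, and 4 without Routine day 7 alone. The Routine samples of days 1 and 7 were the 2 channels of 1 array on slide 2. All untreated and Oryzemate samples of these days lay on slide 1, so on these days Routine and slide could not be told apart. Without 1 of the untreated samples it was 215 (day 1 replicate 1), 112 (day 1 replicate 2), 4 (day 3 replicate 1) and 6 (day 3 replicate 2). It was 681 and 10 without Routine day 3 replicate 1 and 2, and 4 without either Oryzemate sample of day 3. Loess with the 75th percentile gave 0 higher and 1 lower, the processed signal 216 calls, the values deposited by the authors 248 and slide as a block 278. Slide 2 alone gave 0 in limma, in a fit of few samples that says little, with 4185 loci at an unadjusted p under 0.05 in the fit over all slides. Slides 1 and 3 held only 1 Routine sample each. Other probes of the called loci (18 loci) moved by 68.8% of the called probe's change, with 74.4% for 15 rises and 58.6% for 3 falls. The 2 effects share their untreated samples. They correlated at 0.657 (0.476 in simulations without effects), with a covariance of 0.0325 (0.00975 simulated), and 73% of loci had the same sign (65.9% simulated). The untreated samples were also set apart for each treatment, 3 from days 1, 3 and 14 and 4 from days 1, 3, 7 and 30. Each effect then used only the days of its own part. The correlation was 0.062 with Oryzemate set against the first part and 0.679 with it set against the second. Parts and days could not be told apart. Called in both comparisons were 4 higher genes and 1 lower gene, with 0.00997 and 0.00268 for independent lists, which leave out the shared controls. The simulations gave 0 and 0 in limma. Data without effects make such counts nearly certain, so they do not measure what shared controls add.

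**Figure D1:**
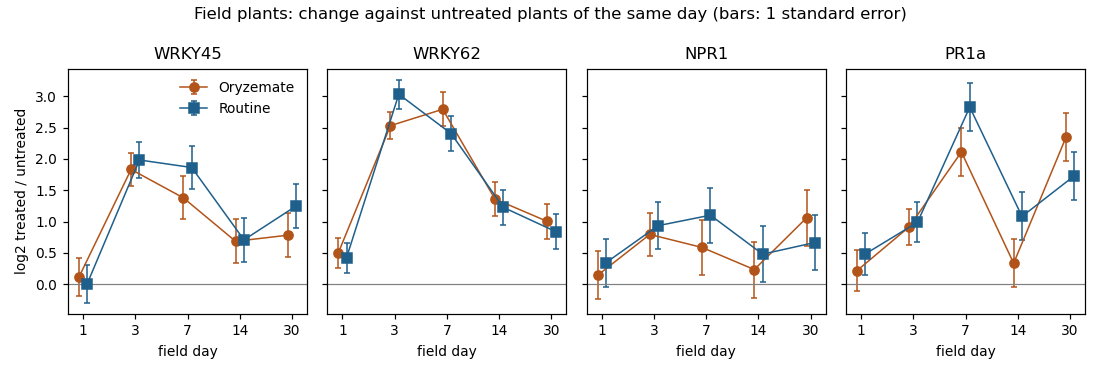
Log2 ratio of treated to untreated field samples (vertical axis) against field day (horizontal axis) for WRKY45, WRKY62, NPR1 and PR1a, with Oryzemate and Routine as separate lines and bars of 1 SE. WRKY62 was at 2.53 with Oryzemate and 3.03 with Routine on day 3, and at 0.50 and 0.43 on day 1.

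Routine and Oryzemate were compared directly on the same field days, at equal weights of granules that carry different amounts of active ingredient (3% isotianil and 24% probenazole). No gene passed in limma (smallest adjusted p = 0.712, with 1821 loci at an unadjusted p under 0.05). The differences, Routine over Oryzemate, were 0.13 for WRKY45 (95% interval -0.51 to 0.76), -0.01 for WRKY62 (-1.04 to 1.03), 0.12 for NPR1 (-0.26 to 0.50), 0.19 for PR1a (-0.59 to 0.96), -0.62 for PR1b (-1.67 to 0.43) and 0.10 for PBZ1/PR10a (-0.32 to 0.52). SGT1 was at -1.20 (-1.98 to -0.43). The genes of smallest p were Os01g0175500 (0.54), the bHLH gene Os01g0195700 (0.45), Os05g0227600, the C-Myc binding gene Os07g0185800 (0.24) and the beta-expansin gene Os10g0555600 (-1.05). Camera called phenylpropanoid entry (-0.34, 0.0449, with adjusted p = 0.792 with an estimated correlation) and peroxidases (median -0.03, mean -0.26, 0.00678, with adjusted p = 0.58 with an estimated correlation), with Os05g0134400 at -1.82. The SA and WRKY45 list was higher with Routine in 4 samples and lower in 2 (-0.2 to 0.391). Without field day 3 the count was 33, and without Oryzemate day 3 replicate 2 it was 1.

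Field day 3 was the time with 2 samples for each treatment, and its effects were compared on their own. With Oryzemate WRKY76 rose by 2.92 (SE 0.249, adjusted p = 0.0315; 12.16 ± 0.34 against 9.29 ± 0.52), WRKY62 by 2.53 (SE 0.21, adjusted p = 0.0295) and SGT1 by 1.86 (at least 2.85-fold). The dioxygenase-family gene Os04g0581100 rose by 2.39 (adjusted p = 0.0148) and the bHLH gene Os01g0108400 by 2.27 (at least 4.74-fold). With Routine WRKY76 rose by 3.43 (adjusted p = 0.0286), WRKY62 by 3.03 (adjusted p = 0.0266), Os04g0581100 by 2.80 (adjusted p = 0.0152), Os01g0108400 by 3.10 and the EGF-like gene Os02g0111600 by 1.30 (adjusted p = 0.0423). The calcium-dependent kinase gene Os03g0789000 fell with Oryzemate (-2.40, at least 4.34-fold) and Routine (-2.46, at least 4.59-fold), as did the spermine synthase gene Os02g0237100 (-1.99 and -1.94). The globin gene Os05g0337100 fell with Oryzemate (-2.17). Each of these genes moved that way in 2 of 2 samples. WRKY45 was at 1.83 (SE 0.265, adjusted p = 0.175) and 1.98 (adjusted p = 0.201), NPR1 at 0.80 and 0.94, PR1a at 0.92 and 0.99, PR1b at 0.68 and 1.07, and PBZ1/PR10a at 0.42 and 0.11, none of them passing. Counts were 33 genes (9 higher, 24 lower) with Oryzemate and 31 (11 higher, 20 lower) with Routine. Both comparisons used the same 2 untreated samples, which were the 2 channels of 1 array. Called in both were 7 higher and 20 lower genes, so the 2 treatments are not independent evidence for these. With probes above background in all 32 samples 1 gene passed in each, and with the processed signal 0 in limma (1249 and 1417 loci at an unadjusted p under 0.05).

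At field day 3 the SA and WRKY45 list had medians of 0.70 and 0.76, with 3 and 2 members risen (5 and 4 over the list alone; camera 7.27e-12 and 1.06e-08, with adjusted p = 0.289 and 0.565 with an estimated correlation). The WRKY family, with medians of 0.08 and 0.21, had 2 risen and 1 fallen in both (2.11e-05 and 4.42e-06, with adjusted p = 0.777 and 0.812 with an estimated correlation). PR proteins (0.42 and 0.51; 5.34e-06 and 0.019, with adjusted p = 0.771 and 0.817 with an estimated correlation), glutathione S-transferases (3.08e-05 and 0.00706, with adjusted p = 0.289 and 0.667 with an estimated correlation) and ribosomal proteins (0.10 and 0.15; 4.97e-07 and 1.82e-07, with adjusted p = 0.804 and 0.853 with an estimated correlation) were called for both. Camera called diterpenoid phytoalexins (0.32, 0.00257), phenylpropanoid entry (0.33, 0.0224) and the circadian clock (-0.16, 0.0192) with Oryzemate and not with Routine. Each had adjusted p = 0.804 with an estimated correlation. A difference between the treatments on this day was not tested. Of the called genes 22 with Oryzemate and 17 with Routine had no sample well above background on 1 side, and other probes of the called loci (8 and 6 loci) moved by 10.9 and 6.49% of the called probe's change. For the rises they moved by 103% (4 loci) and 97.8% (2 loci), and for the falls by 5.81 and 5.73% (4 loci each). The Oryzemate count was 18 without either Routine sample of day 3 and 0 in limma without any other replicated sample (1511 loci at an unadjusted p under 0.05 with all samples). The Routine count was 153 without Routine day 3 replicate 1 and 0 without any other (1693 loci).

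Whether the field effects changed between days 1 to 3 and days 7 to 30 was tested as a difference. No gene passed in limma (smallest adjusted p = 0.116 for Oryzemate and 0.0837 for Routine, with 1192 and 2010 loci at an unadjusted p under 0.05). WRKY45 differed by -0.02 (-0.72 to 0.67) and WRKY62 by 0.21 (-0.35 to 0.76) with Oryzemate, PR1a by 1.03 (0.27 to 1.79) and PR1b by 1.92. With Routine the differences were 1.14 (0.37 to 1.92) for PR1a and 0.77 (0.35 to 1.19) for PBZ1/PR10a. By day (1, 3, 7, 14 and 30), PR1b was at 1.23, 0.68, 1.74, 2.07 and 4.80 with Oryzemate and at 0.69, 1.07, 2.62, 0.41 and 0.98 with Routine. WRKY45 was at 0.11, 1.83, 1.38, 0.69 and 0.78 with Oryzemate and 0.01, 1.98, 1.86, 0.71 and 1.25 with Routine. The genes of smallest p were spermine synthase Os02g0237100 (1.63), DPH2 Os11g0265600 (-1.55) and the zinc finger gene Os09g0551200 (-1.44 with Oryzemate, -1.58 with Routine). Without day 7 the counts were 20 and 30. With loess and the 75th percentile 3734 genes passed for Routine, a scaling that moved the median of all genes by -0.153 (Oryzemate) and -0.185 (Routine).

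**Figure D2:**
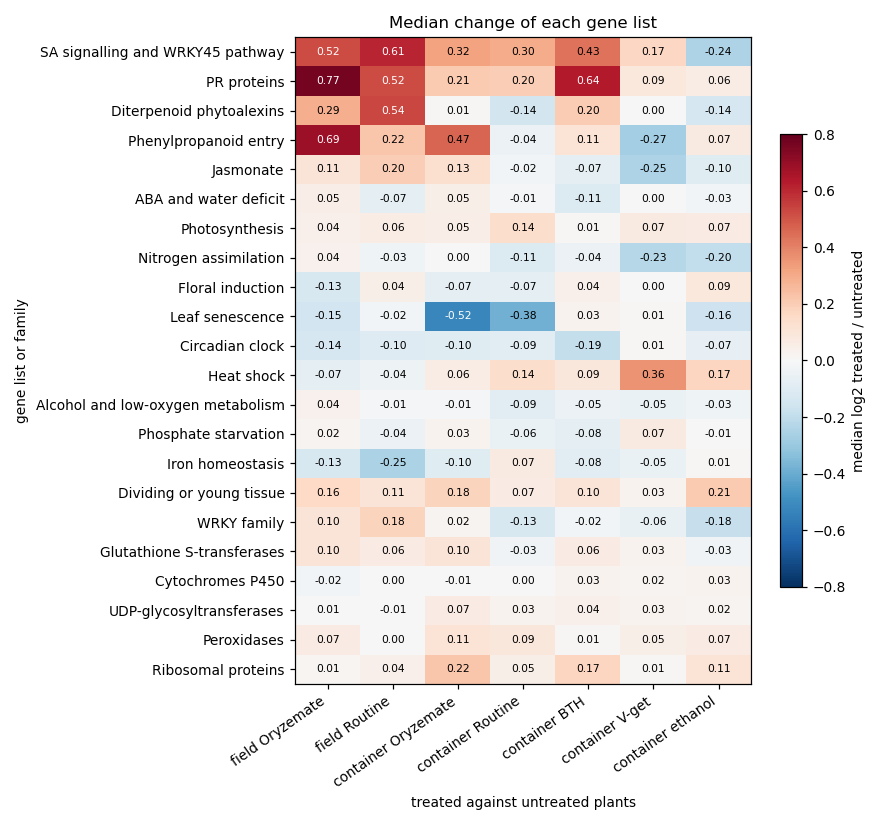
Median log2 ratio (colour and number) of each of 22 gene lists (rows of the map) in 7 comparisons of treated with untreated plants (columns of the map). The SA signalling and WRKY45 pathway list was at 0.52 and 0.61 over the field days and at -0.24 with ethanol in containers; under other scalings the medians of the WRKY family, dividing tissue markers, UDP-glycosyltransferases and peroxidases with Oryzemate and of glutathione S-transferases with Routine turned negative in the field, where loess with the 75th percentile put the median of all genes at -0.107 and -0.112.

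In containers each treatment was compared with untreated containers over days 1 and 3. Untreated and Oryzemate samples lay on slide 3 (74.89 to 80.01% of probes well above background) and the other 4 treatments on slide 4 (79.15 to 86.13%), so slide and treatment could not be separated for these 4. With Oryzemate the carboxypeptidase gene Os05g0153200 rose by 2.06 (adjusted p = 9.81e-08, at least 3.28-fold), the lipid transfer gene Os04g0415900 by 1.81 (at least 2.58-fold) and a peroxidase gene, Os03g0234500, by 1.53 (at least 2.26-fold), and a monooxygenase gene, Os09g0549300, fell by 1.98. The genes named here as risen or fallen in containers moved that way in 2 of 2 samples. With Routine the Myb gene Os02g0114800 rose by 3.10 (SE 0.597, adjusted p = 0.011), the acyltransferase gene Os02g0454500 by 2.11, the NBS-LRR gene Os09g0311600 by 1.87 and the oleosin gene Os04g0546500 by 1.84, the last at -0.16 in the values deposited by the authors. With BTH Os02g0114800 rose by 2.64 (adjusted p = 0.0388), the aspartic peptidase gene Os07g0603500 by 2.27 (adjusted p = 6.33e-08) and a senescence-associated gene, Os06g0653100, by 1.79 (at least 2.80-fold), and the beta-expansin gene Os10g0555600 fell by 1.89, although it was higher by 1.26 in the values deposited by the authors. With V-get Os07g0603500 rose by 1.71, Os05g0146100 by 1.65 (at least 3.10-fold), the small heat shock gene Os06g0253100 by 1.60 (adjusted p = 0.0032) and the heat shock factor gene Os08g0546800 by 1.54 (adjusted p = 0.0298). With ethanol Os07g0693200 rose by 1.44, an invertase inhibitor gene, Os01g0311700, by 1.40 and the nitrate transporter gene Os10g0370700 by 1.13. WRKY62, which did not pass in any of the 5, was at 2.12 with Oryzemate, 1.15 with Routine, 1.44 with BTH, 0.44 with V-get and -0.53 with ethanol. WRKY45 was at 0.63 with Oryzemate, 0.31 with Routine, 0.65 with BTH, 0.10 with V-get and -0.52 with ethanol. In the order Oryzemate, Routine, BTH, V-get and ethanol, PR1a was at -0.22, -0.48, 1.25, -0.32 and -0.55, PR1b at 0.31, 0.18, 0.64, 0.64 and 0.35, NPR1 at 0.05, 0.04, 0.41, 0.13 and -0.21, and PBZ1/PR10a at 0.24, 0.14, 0.36, 0.17 and -0.02, and none of these passed. Counts of higher and lower genes were 61 and 100 with Oryzemate, 109 and 134 with Routine, 113 and 106 with BTH, 93 and 103 with V-get, and 45 and 94 with ethanol.

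Of the lists in containers, SA signalling and WRKY45 was called with Oryzemate (0.32, 12 of 12 genes higher; camera 0.00183, with adjusted p = 0.484 with an estimated correlation). So were PR proteins (0.21, 1 rose; 0.00183, with adjusted p = 0.713 with an estimated correlation), glutathione S-transferases (0.10; 0.0471), peroxidases (0.11, 1 rose; 0.0127, both with adjusted p = 0.484 with an estimated correlation) and ribosomal proteins (0.22; 1.08e-08, with adjusted p = 0.809 with an estimated correlation). In this treatment HSP16.9C fell (-1.10, adjusted p = 0.0264), and SGT1 was at 2.41 (adjusted p = 0.182). Routine had a call for photosynthesis (0.14; 0.0284, with adjusted p = 0.982 with an estimated correlation), where the medians of days 1 and 3 were -0.1 and 0.389, and its SA and WRKY45 median was 0.30. BTH had calls for PR proteins (0.64, 23 of 26 higher; 0.000226, with adjusted p = 0.851 with an estimated correlation), with glucanase Os01g0940800 at 1.73 and RSOsPR10 at 1.41, and for ribosomal proteins (0.17; 9.71e-05, with adjusted p = 0.876 with an estimated correlation). V-get had a call for heat shock (0.36, 11 of 13 higher, 3 over the list alone; 1.98e-05, with adjusted p = 0.185 with an estimated correlation), with HSP24.1 at 1.70 and HSP18.0-CII at 1.21. Ethanol had calls for the WRKY family (-0.18; 0.0385) and ribosomal proteins (0.11; 0.00136), both with adjusted p = 0.991 with an estimated correlation. On days 1 and 3 the medians of PR proteins with BTH were 1.426 and 0.109, and those of ribosomal proteins 0.636 and -0.291 with BTH and 0.43 and 0.003 with Oryzemate. No other scaling turned the sign of these lists.

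The container comparisons share 1 untreated array, which could not be split, and 9 loci rose and 66 fell in all 5, among the latter Os07g0521500 of a disease resistance family, the peptidase gene Os09g0362600 and Os01g0914000. Of the change of these 75 loci 86.5% lay between untreated containers and untreated field plants. Pairs of effects correlated between 0.248 (Oryzemate and BTH) and 0.835 (Routine and ethanol), and simulations without effects gave 0.494 to 0.509. Covariances were 0.0212 (0.0357 simulated) and 0.0617 (0.0344) for these pairs. Oryzemate and Routine correlated at 0.645 (0.504 simulated), BTH and V-get at 0.706 (0.494) and V-get and ethanol at 0.758 (0.502). Both-fallen counts were 72 to 93, with 0.36 to 0.545 for independent lists, which leave out the shared array, so part of the excess may come from it. The simulations gave 0, which data without effects make nearly certain. Other probes of the called loci moved by 8.33% of the called probe's change with Oryzemate, 13.4% with Routine, 12.4% with BTH, 1.07% with V-get and 1.8% with ethanol, and 96, 80, 86, 77 and 49 called genes had no sample well above background on 1 side. Without day 1 and without day 3 the counts were 156 and 77 with Oryzemate, 160 and 88 with Routine, 155 and 162 with BTH, 78 and 86 with V-get, and 101 and 62 with ethanol. With the processed signal 77 genes were higher and 77 lower for Oryzemate and 158 and 94 for Routine; loess with the 75th percentile gave 20 and 36 for BTH, 17 and 29 for V-get and 9 and 36 for ethanol.

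**Figure D3:**
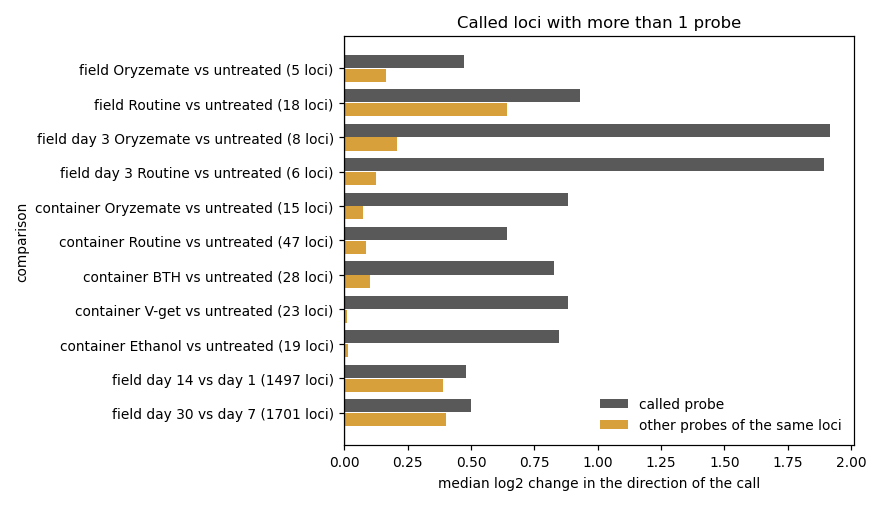
Median change towards the call, in log2 units (horizontal axis), of the called probes and of the other probes of the same loci (separate marks), for each comparison with at least 5 such loci (vertical axis). Other probes moved by 68.8% of the called change for Routine over the field days, 13.4% for Routine in containers and 1.07% for V-get.

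BTH, V-get and Routine were also set against ethanol-treated containers, which uses neither of the untreated container samples. The labels do not say for which of them ethanol was the solvent control. Over ethanol, BTH raised Os06g0653100 by 1.84 (at least 3.58-fold), a prenyltransferase gene, Os03g0728200, by 1.45, the ankyrin gene Os04g0326200 by 1.34, the leucine-rich repeat gene Os11g0568200 by 1.33 and Os07g0603500 by 1.31 (adjusted p = 0.000328). V-get raised Os05g0146100 by 1.77, Dcp1-like Os03g0837000 by 1.40 and Os11g0692100 (adjusted p = 0.015). Routine raised Os02g0454500 by 2.12 (at least 4.35-fold), Os04g0546500 by 1.85, Os09g0311600 by 1.79, the kinesin gene Os01g0513900 by 1.32 and TOM1 by 0.99 (adjusted p = 0.00014). WRKY45 was at 1.17 (0.02 to 2.31) with BTH and 0.83 with Routine. WRKY62 was at 1.96 (0.09 to 3.84), 0.97 (-0.90 to 2.84) and 1.68 (-0.20 to 3.55) with BTH, V-get and Routine. PR1a was at 1.79 (0.39 to 3.19), 0.22 and 0.07, and none of these passed. The SA and WRKY45 list was called with BTH (0.62; 0.0121, with adjusted p = 0.625 with an estimated correlation) and Routine (0.33; 0.00109, with adjusted p = 0.455 with an estimated correlation). BTH also had calls for PR proteins (0.44; 7.67e-05), the circadian clock (-0.16; 0.0121), the WRKY family (0.11; 0.0294) and glutathione S-transferases (0.06; 0.0336), each with adjusted p = 0.625 with an estimated correlation. V-get had calls for heat shock (0.33; 9.19e-08, with adjusted p = 0.0535 with an estimated correlation) and ribosomal proteins (-0.10; 1.45e-07, with adjusted p = 0.763 with an estimated correlation). Of the 2 days, the lower and higher medians with BTH, whichever day they fell on, were 0.025 and 1.341 for PR proteins, -0.361 and -0.065 for the clock and 0.222 and 0.71 for the SA and WRKY45 list. With V-get they were -0.199 and 0.007 for ribosomal proteins and 0.124 and 0.386 for heat shock. Of the called genes 8 with BTH, 1 with V-get and 12 with Routine had no sample well above background on 1 side. Counts were 18 with BTH (17 higher), 9 with V-get and 19 with Routine, all higher. Without day 1 and day 3 they were 21 and 51, 2 and 1, and 14 and 25. The processed signal gave 23 higher and 6 lower, 10 and 2, and 27 and 5, and the values deposited by the authors gave 12 and 2 for V-get and 20 and 3 for Routine.

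BTH, V-get and Routine were compared with each other on matched days, at doses that differed (100 ppm, 3 kg per are and 1 kg per are). BTH over V-get was 0.54 for WRKY45, 0.99 for WRKY62 (-0.88 to 2.87) and 1.57 for PR1a (0.17 to 2.97). BTH over Routine was 0.34 for WRKY45 (-0.81 to 1.49), 0.29 for WRKY62 (-1.59 to 2.16) and 1.72 for PR1a (0.32 to 3.12). V-get over Routine was -0.20 for WRKY45 (-1.35 to 0.95), -0.71 for WRKY62 and 0.15 for PR1a (-1.25 to 1.55), and none of these passed. Genes that did were Os06g0653100, higher with BTH by 1.95 over V-get and 1.90 over Routine, and P450 Os03g0741500, higher by 1.14 with BTH over V-get. TOM1 was lower with BTH (-0.95, adjusted p = 0.000139) and V-get (-0.96) than with Routine. Over both days PR proteins lay higher with BTH than with V-get (0.53, 24 of 26 genes; 1.21e-06, with adjusted p = 0.492 with an estimated correlation) and Routine (0.47; 0.0137, with adjusted p = 0.855 with an estimated correlation). Heat shock genes lay higher with V-get than with Routine (0.31, 13 of 13; 2.7e-05, with adjusted p = 0.2 with an estimated correlation) and lower with BTH than with V-get (0.000135, with adjusted p = 0.409 with an estimated correlation). BTH over V-get also had calls for phenylpropanoid entry (0.22; 0.00297, with adjusted p = 0.52 with an estimated correlation), the circadian clock (-0.17; 0.000308, with adjusted p = 0.492 with an estimated correlation) and ribosomal proteins (0.14; 2.65e-08, with adjusted p = 0.635 with an estimated correlation). BTH over Routine had calls for photosynthesis (-0.11), the clock (-0.12; both 0.0137, with adjusted p = 0.855 with an estimated correlation) and iron homeostasis (-0.07; 0.0318, with adjusted p = 0.266 with an estimated correlation). V-get over Routine had calls for jasmonate (-0.16; 0.0198, with adjusted p = 0.862 with an estimated correlation), photosynthesis (-0.06; 0.0198), ribosomal proteins (-0.06; 0.00822, both with adjusted p = 0.927 with an estimated correlation) and iron homeostasis (median 0.14, mean -0.09; 0.0491, with adjusted p = 0.213 with an estimated correlation).

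Several of these list medians had opposite signs on the 2 days. For BTH over V-get they ran from -0.053 to 1.309 for PR proteins, from -0.425 to 0.016 for the clock and from -0.195 to 0.486 for ribosomal proteins. For BTH over Routine they ran from -0.004 to 1.232 for PR proteins, from -0.313 to 0.064 for photosynthesis and from -0.319 to 0.003 for the clock, and for V-get over Routine from -0.113 to 0.12 for iron homeostasis. Heat shock kept 1 sign, with -0.262 and -0.249 for BTH over V-get and 0.318 and 0.38 for V-get over Routine. Counts for BTH over V-get, BTH over Routine and V-get over Routine were 24 (15 higher, 9 lower), 38 (16 and 22) and 30 (11 and 19). Without day 1 they were 15, 33 and 18, and without day 3 they were 31, 58 and 26. Of these 11, 22 and 14 had no sample well above background on 1 side. Loess with the 75th percentile gave 2 and 2 for BTH over V-get and 2 and 10 for V-get over Routine, and the values deposited by the authors gave 29 and 23 for BTH over Routine.

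The effect of Oryzemate and of Routine in containers was compared with that in the field on days 1 and 3, and no gene passed in limma (smallest adjusted p = 0.0654 and 0.0511, with 1102 and 2317 loci at an unadjusted p under 0.05). Container minus field, WRKY45 was at -0.34 with Oryzemate and -0.69 (-1.56 to 0.18) with Routine, WRKY62 at 0.60 (-0.08 to 1.28) and -0.58, PR1a at -0.79 (-1.73 to 0.16) and -1.21 (-2.16 to -0.26), and SGT1 at 1.11 with Oryzemate. Genes of smallest p included the peptidase gene Os09g0362600 in both (-2.35 with Oryzemate), carboxypeptidase Os05g0153200 (2.25) and Os07g0521500 (-1.88) with Oryzemate, and oleosin Os04g0546500 (1.85) with Routine.

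Field days were compared with each other over all 3 treatments in the additive fit, with 4 samples on day 1 and 3 on each of days 7, 14 and 30. From day 1 to day 14 the amino acid carrier gene Os05g0424000 fell by 3.57 (SE 0.356, adjusted p = 3.39e-06), and so did aspartokinase Os09g0294000 (-2.59), PAL Os12g0520200 (-2.53) and LHY (-2.14, adjusted p = 8.35e-06). Each gene said here to have risen or fallen between days did so in 3 of 3 treatments. Of the nitrogen assimilation list (median -0.37) 5 fell and 1 rose, with NIA1 at -1.76 (adjusted p = 1.13e-06), NIA2 at -1.72, GS1;2 at -1.45 and AMT1;1 at -1.39 (camera 0.00177, with adjusted p = 0.0252 with an estimated correlation). Photosynthesis genes had a median of -0.40 and 6 fell (8 over the list alone), LHCB Os03g0592500 by 0.77 (camera 2.54e-05, with adjusted p = 0.717 with an estimated correlation). Of the clock genes (-0.26) 4 fell, PRR73 by 0.73 (0.00846, with adjusted p = 0.657 with an estimated correlation). Of the heat shock genes (0.54) 5 rose, HSP17.9 by 1.49 and HSP101 by 1.15 (0.00857, with adjusted p = 0.629 with an estimated correlation). Ribosomal proteins had 3 risen and 1 fallen (0.19; 0.00177, with adjusted p = 0.906 with an estimated correlation). Floral induction genes, which camera did not call (0.323), had Ehd1 risen by 1.17 and MADS50 fallen by 0.68. Other large rises were those of Os07g0598000 (2.22), Os01g0106400 (2.19), the kinase gene Os11g0691500 (2.18), lipid transfer Os05g0550300 (1.95) and ferredoxin Os07g0489800 (1.93). In all 4527 genes passed (2344 higher, 2183 lower), and the other probes of 1497 called loci moved by 81.2% of the called change. Loess with the 75th percentile, which shifted the median of all genes by 0.147, gave 3922 higher and 1500 lower, and slide as a block gave 2861.

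From day 7 to day 30 heat shock genes rose in 9 of 13 cases (median 1.66), HSP24.1 by 3.36 (adjusted p = 2.13e-07), HSP101 by 2.57 (adjusted p = 1.31e-09), HSP18.0 by 2.43 and HSP17.4 by 2.30, and camera gave 3.18e-09, with adjusted p = 0.0158 with an estimated correlation. Outside the list the immunophilin gene Os04g0352400 rose at least 24.2-fold, the heat shock factor gene Os09g0526600 by 3.31, Hsp20 Os06g0253100 by 3.05 and HSP70 Os01g0840100 by 2.92. Of 19 jasmonate genes 17 fell (median -1.34; 19 over the list alone), among them JAZ11 (-3.48, adjusted p = 1.42e-07), LOX Os12g0559200 (-3.47) and JAZ12 (-2.67; camera 4.24e-15, with adjusted p = 0.0158 with an estimated correlation). Other falls were those of Os12g0247700 (-4.86), the PR1 gene Os07g0129300 (-4.75), the Bowman-Birk inhibitor genes Os01g0132000 (-4.20) and Os01g0124000 (-3.80), and the terpene synthase gene Os08g0168000 (-3.66, at least 11.4-fold). Of the WRKY family (median -0.30) 19 fell and 2 rose, WRKY13 falling by 0.95 (0.000124, with adjusted p = 0.177 with an estimated correlation). Phenylpropanoid entry (-1.21, 6 fell), the SA and WRKY45 list (-0.77, 3 fell) and diterpenoid phytoalexins (-0.36, 6 fell) were called with 0.000144, 0.000761 and 0.0168, with adjusted p = 0.262, 0.177 and 0.541 with an estimated correlation. These medians average treated and untreated plants, so a change with day was not separated from a change in the treatment effect between these days. Photosynthesis genes were higher in 26 of 26 cases and 9 rose, RCA by 1.02 (7.35e-05, with adjusted p = 0.518 with an estimated correlation). Peroxidases, whose median of -0.07 became 0.34 under 1 other scaling, had 5 fallen (0.0327, with adjusted p = 0.481 with an estimated correlation). Floral induction genes had 4 risen and 3 fallen, with MADS15 at 2.06, Ehd1 at 1.94 (at least 3.62-fold) and Hd1 at -1.25. PR proteins had 1 risen and 4 fallen (median 0.15, mean -0.16). In all 5516 genes passed (2969 higher, 2547 lower). Loess with the 75th percentile, which shifted the median of all genes by 0.143, gave 4401 higher and 1387 lower.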

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

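Of the tests below, those of the single untreated container array (2 tests), of one field day alone, and of the rises and the falls at field day 3 taken separately were chosen after the result was seen.

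The calls that concerned single arrays formed the first pattern weighed. In the container comparisons against untreated plants the other probes of 64 called loci moved by 15.1% of the called probe's change (0.102 against 0.677, with the same sign for 48), and at field day 3 those of 8 called loci moved by 10.3%, all 8 with the same sign. The same measure came to 80.0% between field days 30 and 7 (1581 of 1701 loci), which argues against this explanation there. Over field days 1 to 30 it came to 68.3% (19 of 19 loci with the same sign). Of these, 18 loci were Routine calls (68.8% for Routine alone), and for them it argues against this explanation as well. For the Oryzemate calls alone it was 34.6% on 5 loci, between the limits of 25 and 50%, so it could not tell. A candidate explanation for the container calls on these 64 loci is that spots or probes of one array read high or low in both channels. The tested probe was by rule the brightest of its locus, so dimmer probes might also miss a real change. Of the container calls 32.9 to 59.6% had no sample well above background on 1 side, against 0 and 1.61% over the field days. The measure cannot tell these apart. For the 75 loci called in the same direction for all 5 treatments, 86.5% of the change (bootstrap interval over loci 79.7 to 98.0) lay between the untreated containers and untreated field plants of the same days, so these calls may come from the single untreated array or the plants on it. Loci picked for moving alike against that array tend to a large share by the choice itself. The interval covers the spread between loci, not that between arrays or plants. Over all 406 called loci, these 75 included, the share was 23.3% (17.2 to 28.9). The rest were not measured apart, so the question stays open for them. Slide and treatment cannot be told apart for BTH, V-get, Routine and ethanol against untreated containers, and too few loci decided for calls against ethanol (-3.91% on 2 loci) and for the rises and falls at day 3 (98.3 and 5.12% on 4 loci each).

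The second pattern was the SA signalling and WRKY45 pathway list, whose medians were 0.52 with Oryzemate and 0.61 with Routine over the field days. A difference between slides was argued against by a median that stayed at 0.451 or above in both treatments with slide as a block, and an effect of one field day alone by a lowest median of 0.428 over the fits that left out 1 day. As a hypothesis found and tested on the same data, both treatments may raise these genes in the field. The untreated samples were shared between the treatments, and an undescribed difference between field sections remained untested.

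The third pattern was the rise of heat shock genes and the fall of jasmonate genes between field days 7 and 30. With slide as a block the medians were 1.446 and -1.118, which argues against a difference between slides, and the other probes of the called loci moved by 80.0% of the called change. All samples of day 30 lay on slide 2, where the only sample of day 7 was the Routine sample that stood apart. The separation of slide and day therefore leaned in part on that sample. As a hypothesis, the 2 lists may follow the conditions at sampling or the age of the leaf, which 3 samples on each of 2 days cannot tell apart.

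The results that follow were noted because a tested difference between time groups or between containers and field passed for a gene list. For the Oryzemate effect, days 7 to 30 minus days 1 to 3, the PR proteins differed by 0.286 (camera 0.000136, with adjusted p = 0.665 with an estimated correlation). Loess with the 75th percentile, the scaling named next, shifted the median of all genes by -0.153 here, to -0.163. Diterpenoid phytoalexins differed by 0.24, with a negative value (-0.02) under that scaling (camera 0.000488). Phenylpropanoid entry differed by 0.771 (camera 0.000136), and jasmonate by 0.179 (camera 0.000423). The WRKY family differed by 0.054, with -0.20 under it (camera 0.0449), cytochromes P450 by 0.055, with -0.19 under it (camera 0.0323), and peroxidases by 0.098, with -0.49 under it (camera 0.0143). Ribosomal proteins differed by -0.263, with 143 of 146 genes lower (camera 7.66e-18, with adjusted p = 0.78 with an estimated correlation). For the Routine effect over the same days diterpenoid phytoalexins differed by 0.444 (camera 8.27e-05), phenylpropanoid entry by 0.436 (camera 0.00196), jasmonate by 0.248 (camera 0.00505), heat shock by -0.223 (camera 0.0164) and ribosomal proteins by -0.096 (camera 0.00303). For the Routine effect in containers minus that in the field on days 1 and 3, the WRKY family differed by -0.292 (camera 0.000218) and peroxidases by 0.164 (camera 0.0184). With an estimated correlation the adjusted p of these 15 lay between 0.566 and 0.914, and with fry between 0.5 and 0.935.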

How the results depend on the processing

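Among the alternatives below, the filter on all 32 samples, the omission of Routine field day 7 and the crossed replicate block were chosen after the result was seen. Counts follow as called genes, the cause of a change was not tested except where fewer samples or loci make it plain, and signal over background limited dim probes, for which a smaller set of loci was tested under stricter filters. Of 5703 values of named genes under an alternative, 4628 kept their direction and their side of the threshold. With the direction kept, 960 no longer passed and 28 newly passed. A further 83 that had not passed in the reported fit changed sign, and 4 that had passed reversed. The medians of the SA and WRKY45 list lay between 0.389 and 0.718 with Oryzemate and 0.409 and 0.844 with Routine over all settings.

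With the processed signal the counts were 109 for Oryzemate and 216 for Routine over the field days, 0 for both at field day 3 (1511 and 1693 loci at an unadjusted p under 0.05 in limma with the reported scaling), 29 for BTH over ethanol, 32 for Routine over ethanol and 61 for BTH over Routine. With loess and the 75th percentile they were 0 for Oryzemate and 1 for Routine in the field, 3734 for the late minus early Routine effect, and 38, 76, 56, 46 and 45 for Oryzemate, Routine, BTH, V-get and ethanol over untreated containers. That scaling gave 3, 1 and 10 for BTH, V-get and Routine over ethanol, 4 for BTH over V-get, 19 for BTH over Routine, 12 for V-get over Routine, and 18 for Routine in containers minus field. With the authors' value table the counts were 316 and 248 for Oryzemate and Routine in the field, 21 for Oryzemate at day 3, 46 and 56 for the late minus early effects, 29 and 14 for BTH and V-get over ethanol, and 54 and 59 for containers minus field. That table also reversed 4 values: Os04g0546500 was at -0.16 for Routine over untreated containers and at 0.15 for BTH over Routine, and Os10g0555600 was at 1.26 and 2.49 for BTH and V-get over untreated containers.

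With probes above background in 16 of 32 samples the counts were 182 and 312 for Oryzemate and Routine in the field, 10 and 16 at day 3, and 45, 101, 96, 85 and 55 for Oryzemate, Routine, BTH, V-get and ethanol over untreated containers. They were 9, 3 and 0 for BTH, V-get and Routine over ethanol, and 7, 7 and 4 for BTH over V-get, BTH over Routine and V-get over Routine. With probes above background in all 32 samples the counts in the same order were 295 and 374, 1 and 1, then 26, 70, 65, 53 and 36, then 6, 0 and 0, and 1, 4 and 0. Without a filter, Routine in containers minus field had 5.

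Without the array block the counts were 2285 and 1559 for Oryzemate and Routine in the field, 2 for Routine over Oryzemate, and 419, 869, 628, 432 and 322 in the order of containers given above. They were 37, 19 and 29 over ethanol, 41 for BTH over V-get, 60 for BTH over Routine, and 7 and 10 for containers minus field. Without the dye term they were 21 and 417 in the field, 68 and 69 at day 3, 16 and 34 for late minus early, and 27 and 38 for containers minus field. With slide as a block they were 1792 and 278 in the field, 56 and 68 at day 3, 272 for Oryzemate over untreated containers, 30 for BTH over ethanol and 2861 for day 14 over day 1. Within slides 1 and 2 alone they were 0 for Oryzemate, and within slide 2 alone 0 for Routine, in limma (4996 and 4185 loci at an unadjusted p under 0.05 over all slides). These fits held few samples, so counts of 0 in them say little. The slide block could not be fitted for the other container treatments over untreated, nor for the late minus early and the container minus field effect of Routine.

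Without Routine field day 7 the counts were 130 for Oryzemate and 4 for Routine. With the replicate number as a block at field day 3 they were 18 for Oryzemate and 153 for Routine, and the deviations of samples with the same number correlated at -0.043 (untreated and Oryzemate), -0.375 (untreated and Routine) and 0.49 (Oryzemate and Routine), so that the numbers were not taken to pair the samples. Oryzemate and Routine replicate 1 were the 2 channels of 1 array and their replicates 2 lay on slide 1, while both untreated replicates shared an array of slide 3. As both Routine samples of day 3 were Cy5, the dye term turned the replicate block into the omission of Routine replicate 1. The block with the numbers crossed likewise became the omission of Routine replicate 2. Neither block was therefore a test of pairing. Leaving out each day or replicated sample in turn gave 0 to 119 for Oryzemate and 2 to 681 for Routine in the field, 0 to 33 for Routine over Oryzemate, 0 to 18 and 0 to 153 at day 3, 0 to 20 and 0 to 30 for late minus early, 3889 to 4515 for day 14 over day 1, and 5098 to 5541 for day 30 over day 7. In containers it gave 77 to 156, 88 to 160, 155 to 162, 78 to 86 and 62 to 101 over untreated, 21 to 51, 1 to 2 and 14 to 25 over ethanol, and 15 to 31, 33 to 58 and 18 to 26 between compounds. It gave 0 in limma for containers minus field (1102 and 2317 loci at an unadjusted p under 0.05). A sample left alone in its group was assumed to vary like the others. Of 95 list results that camera called, 8 passed with an estimated correlation, and fry called 20.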

Other observations

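Of the tests below none was chosen after its result was seen, and the genes of the next paragraph follow the naming rule.

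Abscisic acid genes changed in both directions between field days 7 and 30, 3 rising and 4 falling, with ABA8ox1 at -3.36 (adjusted p = 2.65e-05) and ABA8ox3 at 1.70. In the nitrogen list NIA1 rose by 0.82 and NADH-GOGAT1 fell by 1.45. Cytochromes P450 had 12 risen and 30 fallen between these days, UDP-glycosyltransferases 12 and 8, and glutathione S-transferases 4 and 9, while between days 1 and 14 they had 20 and 19, 6 and 8, and 6 and 1. In the abscisic acid list DREB1A fell by 1.60 from day 1 to day 14 (adjusted p = 0.00355).

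By container day, WRKY62 was at 2.36 on day 1 and 0.51 on day 3 with BTH, at 1.47 and 2.76 with Oryzemate, and at 0.20 and 2.10 with Routine. The median of the SA and WRKY45 list was 0.17 and 0.56 with Oryzemate, -0.01 and 0.54 with Routine, -0.06 and 0.44 with V-get, and -0.42 and -0.03 with ethanol. PR proteins with BTH had medians of 1.43 on day 1 and 0.11 on day 3. A difference between these days was not tested.

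Other groupings of the same samples, within field days, were fitted for the field comparisons. For Oryzemate 2 of 100 groupings, the real one included, gave at least the 12 real calls, and the highest other gave 16. That share is under 0.05, but the groupings took no account of slide, so chance was not taken as excluded. The grouping with 16 calls kept all Oryzemate samples together except that untreated day 3 replicate 1 took the place of Oryzemate day 3 replicate 2; both samples of day 3 in it were Cy3 on slide 3, and the count with slide as a block was 1792. For Routine 2 of 100 gave at least the 62 real calls, and the highest other gave 478. It moved untreated replicate 1 of days 1 and 3 to the Routine side and Routine day 3 replicate 1 to the untreated side. A count of several times the real one points to a structure of the samples besides the treatment, and slide as a block gave 278. For Routine against Oryzemate 48 of 48 groupings gave at least the 0 real calls of limma (1821 loci at an unadjusted p under 0.05), which a count of 0 makes certain, so that these groupings say nothing about chance. The highest other gave 972, and it joined the day 3 samples of slide 1 and the 2 Routine samples that shared an array of slide 2, which again points to a structure of the samples. Between days 14 and 1, 1 of 35 groupings, the real one, gave the 4527 calls, and the highest other gave 1114. That share is under 0.05, again for groupings that took no account of slide. Between days 30 and 7 there were 10 groupings, too few for a share under 0.05, and 1 gave the 5516 real calls, with 4 in the highest other.

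The other pairs of container effects correlated at 0.339 (0.501 simulated) for Oryzemate and V-get, 0.581 (0.494) for Oryzemate and ethanol, 0.535 (0.5) for Routine and BTH, 0.719 (0.502) for Routine and V-get, and 0.47 (0.501) for BTH and ethanol. Their covariances were 0.0246 (0.035 simulated), 0.0456 (0.0343), 0.0431 (0.0347), 0.0492 (0.0349) and 0.0313 (0.0348). For the pairs given above they were 0.0614 (0.0352) for Oryzemate and Routine, 0.0435 (0.0344) for BTH and V-get and 0.0428 (0.0348) for V-get and ethanol. Counts risen in both members of a pair were 9 to 67, with 0.105 to 0.472 for independent lists, which leave out the shared array. The simulations gave 0, which data without effects make nearly certain. With the untreated field samples in separate parts, whose days differed, the Oryzemate and Routine effects had covariances of 0.00481 and 0.0294. Of the loci 55.9 and 69.7% had the same sign.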
